A study of Caenorhabditis elegans with 4 samples.

How the data were processed

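The series comprises 4 ChIP-seq libraries from L2 hermaphrodites of strain OP86, 2 from anti-GFP immunoprecipitation of PEB-1::GFP and 2 inputs. Per the labels' protocols, worms were grown at 20 °C on plates seeded with bacteria and crosslinked with 2% formaldehyde. Chromatin was sheared by sonication, and part of each lysate was kept as input before affinity-purified anti-GFP antibody was added. Samples were grouped as ChIP or input, with replicate numbers 1 and 2, from their titles.

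The deposited files are 3 peak lists, for ChIP replicate 1, ChIP replicate 2 and a combined analysis. Per the file headers, coordinates are on WormBase build WS220, and the source field of each line names the peak caller PeakSeq, which compares ChIP reads with a control library. The authors' value for each peak is a q-value, and every q-value in the 3 lists is below 0.01. No fold enrichment, read count or summit is given in these lists. The aligner, the version and settings of the caller, the read depth, and the way in which the replicates were merged for the combined list are not given in the sources used here. The lists are thus 1 per replicate and 1 for the combined analysis, with no common scale of enrichment. Because a q-value depends on read depth, differences in peak number between lists can arise from depth as well as from binding. The deposited q-values were used only to rank peaks, to describe them, and to compare groups of peaks within the combined list and overlapping peaks between lists. Adjacent peaks of a list lie at least 200 bp apart, so closer peaks are absent from the lists.

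Widths are inclusive of both end positions, and −log10 q was computed from the deposited q-values. Overlap between lists required at least 1 bp. The overlap of the replicates was tested with 100000 random rotations of the replicate 1 peaks within each chromosome, one-sided. The difference in median −log10 q between combined peaks in both replicates and the others was tested as planned with 100000 permutations over peaks, two-sided, but no p-value is reported for it, because the groups and the values come from the same ChIP libraries. The shares of peaks on chromosome X and in the central part of the autosomes were set against their share of length with two-sided exact binomial tests. Chromosome length was taken as the end of the last peak on that chromosome in any list, since no WS220 sequence was used here. Intervals are 95% exact (Clopper-Pearson) intervals and cover counting error in the number of peaks only. The 4 planned tests, including that of the −log10 q difference, were adjusted together by the Benjamini-Hochberg method. Because the −log10 q test was bound to pass, including it can make the adjusted p-values of the others slightly smaller. Analyses used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and figures used Matplotlib 3.10.9.

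The tests were run on simulated lists first. For the replicate overlap, 73 of 73 planted shared peaks were recovered in a list of 147, and 1 of 20 pairs of unrelated lists passed the threshold of 0.05. Each planted peak was given the start of a simulated replicate 1 peak, so its overlap was certain and its recovery checks only the counting. For the share on X, 9 of 200 uniform draws passed, and 172 of 200 passed when density on X was raised 1.2 times. For the central part of the autosomes, 10 of 200 uniform draws passed. The simulated peaks were placed independently, whereas the deposited combined peaks lie closer together than uniform placement gives. These rates therefore do not give the error rate for clustered peaks.

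The main set of peaks named in the text followed a rule fixed before the data were examined: the 20 with the lowest q-values in the combined list among those that overlap a peak in both replicate lists. The other peaks named, such as the wide regions near the right ends of chromosomes I and V, the strong peaks missing from 1 replicate and those of the closing section, were chosen after their values were seen. The designs and most alternatives were also fixed before the data were examined. The alternatives were other overlap criteria, the stronger 50% of each list, equal list lengths, each replicate list in place of the combined list, and only peaks in both replicates. Further alternatives, chosen after seeing the data, left out peaks of 1000 bp or more, peaks under 50 bp, or chromosome I, or merged peaks within 1000 bp, and every chromosome was also set against its span. A gene annotation or genome sequence of build WS220 was not used here, and the gene table at hand follows another assembly (WBcel235), so no peak was assigned to a gene. For this reason 6 planned results were not run: the share of peaks in promoters, the 20 gene lists, noncoding genes, a PEB-1 consensus sequence, short sequence words, and peaks at the loci carried by the transgene (peb-1 and unc-119). Peaks at myo-2, ceh-22 and pha-4 were not analysed for the same reason.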

Results

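Binding of the transcription factor PEB-1 was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in hermaphrodite Caenorhabditis elegans at the second larval stage (L2). PEB-1 is a DNA-binding protein with a FLYWCH zinc finger that is expressed in the pharynx, the feeding organ of the worm. The strain, OP86, carries a peb-1 transgene tagged with EGFP, and an antibody against GFP was used to recover the DNA bound by the fusion protein. The series holds 4 libraries, which are 2 ChIP libraries and 2 inputs (total chromatin set aside before the antibody step). The measurements are the authors' peaks, each a genomic interval on WormBase build WS220 with a q value. The replicate 1 list holds 1095 peaks, the replicate 2 list 153 peaks, and the combined list 1854 peaks. The inputs have no list of their own here, and the read depth of the 4 libraries is unknown. The labels do not say whether the replicates were separate cultures, so their spread may be technical.

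The first comparison asked how many regions each analysis marked and how strong they were. The strongest peak of the combined list covered 11753 bp on chromosome X (2206318 to 2218070, q = 4.36e-122). The strongest peak of each replicate was instead a region near the right end of chromosome I. In replicate 1 it ran from 15063994 to 15067640 (q = 1.23e-60), and in replicate 2 from 15063996 to 15067643 (q = 5.44e-33). The right end of chromosome I carries the ribosomal RNA gene array, and whether this region lies within it was not analysed here. No peak of the combined list overlapped this region, and the last combined peak on chromosome I ended at 14948222. The X region was among the 3 strongest in both replicates, with a best q value of 4.32e-59 in replicate 1 and 2.53e-31 in replicate 2.

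Most peaks were short. The median width was 199 bp in replicate 1, 120 bp in replicate 2 and 155.5 bp in the combined list. Peaks under 50 bp made up 14.2% of the replicate 1 list, 26.1% of the replicate 2 list and 25.2% of the combined list, and the shortest combined peak was 2 bp. The lists covered 260.5 kb, 216.8 kb and 362.6 kb of the genome. A single replicate 2 peak on chromosome V (20748394 to 20924161) spanned 175768 bp, and without it replicate 2 covered 41.0 kb. Replicate 1 had 1 peak of 134 bp within this stretch, and the combined list had 3 peaks that together covered 349 bp. Peaks with a q value below 1e-05 numbered 137 in replicate 1, 7 in replicate 2 and 340 in the combined list. With 1 list per replicate, the difference in peak number between the replicates has no test.

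**Figure D1:**
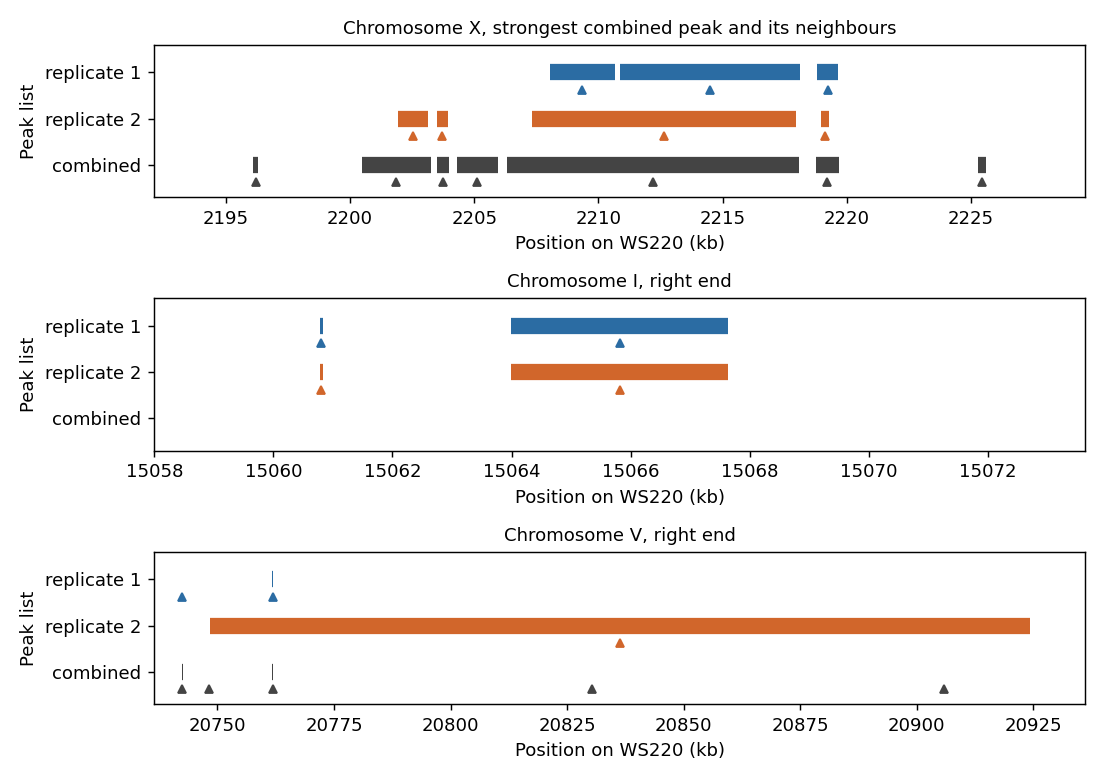
Peaks of the 3 lists (rows) at 3 places on WS220 (x axis, kb), where bars are drawn to scale and triangles mark peak midpoints so that short peaks stay visible. The X region is present in all 3 lists, the chromosome I region in both replicates but not in the combined list, and the stretch of 175768 bp on chromosome V in replicate 2 alone.

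The second comparison asked whether the replicates marked the same places. Of the 153 replicate 2 peaks, 86 overlapped a replicate 1 peak by at least 1 bp (56.2%, 95% exact binomial interval 48.0 to 64.2). Rotating the replicate 1 peaks around each chromosome gave a mean overlap of 1.0%, and none of 100000 rotations reached the observed share (one-sided permutation p = 1e-05, the smallest these rotations can give; adjusted p = 2e-05 over 4 tests). In the other direction, 87 of the 1095 replicate 1 peaks (7.95%, interval 6.41 to 9.71) overlapped replicate 2. Among the strongest replicate 1 peaks, 16 of the first 20 and 46 of the first 100 overlapped replicate 2. Among replicate 2 peaks, 18 of the first 20 and 58 of the first 100 overlapped replicate 1, as did 28 of the remaining 53 (52.8%, interval 38.6 to 66.7). Across 81 overlapping peaks shorter than 1000 bp, the −log10 q values of the replicates correlated, with Spearman's rho = 0.52 and Pearson's r = 0.63 (permutation p = 1e-05 for each). Without the 2 peaks farthest from the replicate 1 median, r was 0.63. These are correlations across peaks, which are not independent replicates. When replicate 1 was limited to its 153 strongest peaks, the overlap was 33.3%.

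The third comparison set the combined list against the replicates. The combined peaks that overlapped both replicate lists numbered 87 (4.69%, interval 3.78 to 5.76). A further 804 overlapped replicate 1 only, 44 overlapped replicate 2 only, and 919 (49.6%, interval 47.3 to 51.9) overlapped neither. Conversely, 893 of the 1095 replicate 1 peaks (81.6%) and 129 of the 153 replicate 2 peaks (84.3%) overlapped a combined peak. The 87 combined peaks found in both replicates had a median −log10 q of 7.89, against 3.26 for the other 1767, a difference of 4.63. Peaks called in both replicates are bound to score higher in a list made from the same ChIP libraries, so this difference is a description and carries no test. Those 87 peaks were also wider, with a median of 377 bp against 145 bp. Wide peaks meet an overlap of 1 bp more easily, so this too is only a description. The 919 peaks found in neither replicate had a median width of 66 bp, and 399 of them (43.4%) were under 50 bp. All of the 20 strongest combined peaks overlapped replicate 1 and 15 overlapped replicate 2. Among the 927 weakest combined peaks, 28.7% overlapped replicate 1 and 2.91% overlapped replicate 2. The combined list rests on the same ChIP libraries as the replicate lists, so the shares are not independent evidence of binding either.

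**Figure D2:**
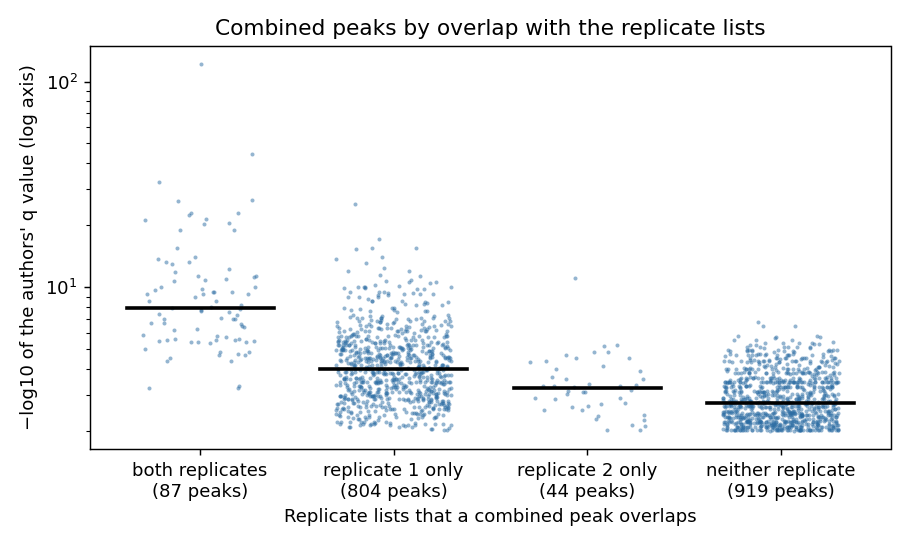
The −log10 of the authors' q value (y axis, log scale) for each combined peak, by the replicate lists it overlaps; each point is 1 peak and the black line is the median. The median falls from 7.89 for the 87 peaks in both replicates to 2.75 for the 919 in neither.

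The 20 strongest combined peaks present in both replicates lay on chromosomes I, II, III, V and X. Chromosome X held 7 of them. The region at 2206318 to 2218070 came first, followed on X by 10568397 to 10569138 (q = 2.23e-27), 5811886 to 5812453 (q = 1.26e-23) and 5840873 to 5841461 (q = 6.36e-22). The remaining X peaks were at 5475053 to 5475657, 11474071 to 11474634 and 12655077 to 12655820. Chromosome I held 3, and the peak at 9380968 to 9382021 had rank 2 in the combined list (q = 2.20e-45) and rank 5 in both replicates. The other peaks on chromosome I were at 1068083 to 1068592 and 10769752 to 10770145. On chromosome II the peak at 1237909 to 1238367 had rank 3 (q = 4.02e-33), ahead of those at 10502617 to 10503098, 9282662 to 9283126 and 66316 to 66767. On chromosome III the strongest lay at 8801374 to 8802229 (q = 4.10e-27), ahead of 1925060 to 1925552, 4281922 to 4282528 and 4560366 to 4560909. Chromosome V held those at 14366344 to 14367092 and 6541597 to 6542240, and chromosome IV held none of the 20. These peaks had a median width of 578.5 bp. All 20 stood among the 100 strongest of replicate 1, and 14 among the 50 strongest of replicate 2.

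Of the 20 strongest combined peaks, whether in both replicates or not, 5 were missing from replicate 2, and they are named here after their values were seen. The strongest was on chromosome IV at 14032525 to 14034479 (q = 3.65e-26), a region of 1955 bp that had rank 7 in replicate 1. The others lay on chromosome II at 11619873 to 11620483, on chromosome I at 7500383 to 7500950, and on chromosome X at 4962252 to 4962720 and 16929498 to 16931456. In the opposite case, the strongest combined peak found in replicate 2 but not in replicate 1 lay on chromosome I at 12093504 to 12094322 (q = 7.52e-12), where the replicate 2 q value was 0.00228.

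The fourth comparison asked how the peaks were spread over the chromosomes. Chromosome X held more peaks than its length would give in all 3 lists, and in single lists other chromosomes did too. X carried 380 of the 1854 combined peaks (20.5%, interval 18.7 to 22.4) against 17.6% of the genome span (two-sided exact binomial test, p = 0.00152, adjusted p = 0.00152 over 4 tests). In replicate 1, 230 of 1095 peaks lay on X (interval 18.6 to 23.5, exact p = 0.00427). In replicate 2, 42 of 153 did (27.5%, interval 20.6 to 35.2, exact p = 0.00275). Among the 87 combined peaks present in both replicates, 25 lay on X (28.7%, interval 19.5 to 39.4, exact p = 0.0106). Each of the 6 chromosomes was then set against its span in each list, a comparison chosen after the data were seen (two-sided exact binomial tests, adjusted over the 6 chromosomes of a list). In the combined list, chromosome I held 21.6% of peaks, 1.44 times its share of the span (adjusted exact p = 2.93e-13), a larger excess than that on X (1.16 times, adjusted exact p = 0.00228). Chromosome I was not above its span in replicate 1 (14.3%, adjusted exact p = 0.554) or replicate 2 (9.80%, adjusted exact p = 0.212). In replicate 1, chromosome II held 18.4% of peaks against 15.2% of the span (adjusted exact p = 0.00967) and chromosome III 16.2% against 13.8% (adjusted exact p = 0.0308), beside the excess on X (adjusted exact p = 0.00967). Chromosome V held fewer peaks than its span in replicate 1 (15.3% against 20.9%, adjusted exact p = 1.35e-05) and in the combined list (15.3%, adjusted exact p = 3.24e-09). Chromosome IV was also below its span in the combined list (13.2% against 17.4%, adjusted exact p = 1.86e-06) and in replicate 1 (14.9%, adjusted exact p = 0.0308). In replicate 2 only X passed (adjusted exact p = 0.0165), on 153 peaks. Whether the lists differ from each other in these shares was not tested. The test treats peaks as independent, although peaks lie in clusters.

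Chromosome I carried 401 combined peaks, or 26.6 per Mb, the highest density of the 6 chromosomes in that list, while in replicate 1 it carried 157, or 10.4 per Mb, below chromosomes II, III and X. In replicate 2 it carried 15 peaks, or 0.996 per Mb, the lowest density of the 6. Of the combined peaks on chromosome I, 263 of 401 (65.6%) overlapped neither replicate, against 656 of 1453 (45.1%) on the other chromosomes (two-sided Fisher's exact test, adjusted p = 2.22e-12 over 6 chromosomes). Among combined peaks that overlapped replicate 1, −log10 q was higher than in replicate 1 by a median of 2.36 on chromosome I (135 peaks, quartiles 1.62 to 3.57), and by 0.79 on the others (756 peaks, quartiles 0.29 to 1.49). This test and this difference were chosen after the counts were seen. With only 157 replicate 1 and 15 replicate 2 peaks on chromosome I, most of its 401 combined peaks could hardly overlap either list. The test therefore mostly restates the surplus and is not separate evidence. With chromosome I left out, the share of combined peaks on X was 26.2% against 20.8% of the span. Leaving out a chromosome with an excess raises the ratio of share to span on all others, so this is no separate support.

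**Figure D3:**
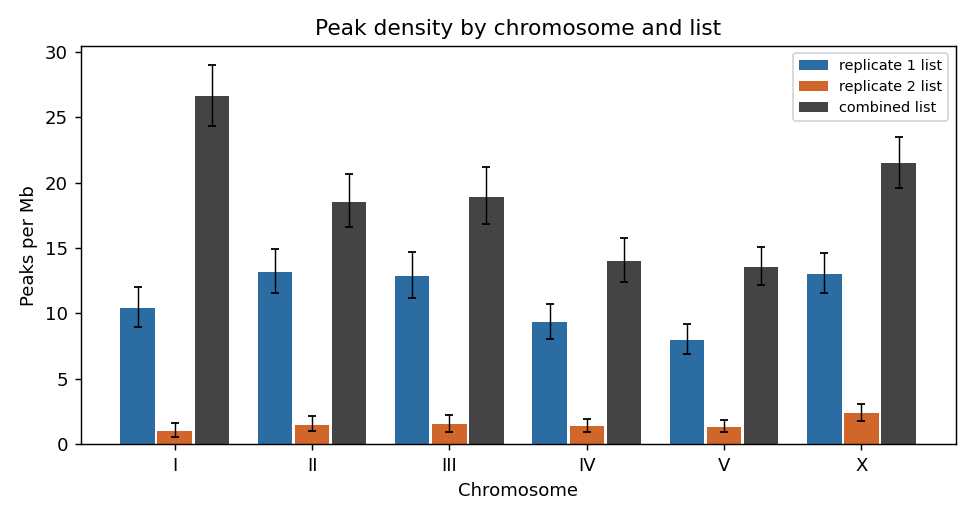
Peaks per Mb of chromosome span (y axis) for each chromosome and list; bars start at 0 and error bars are 95% exact binomial intervals of each chromosome's share of its list. Chromosome I stands at 26.6 peaks per Mb in the combined list and at 10.4 in replicate 1, and chromosome X is the highest in replicate 2 at 2.38.

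On the 5 autosomes, peaks were more frequent near the middle. The central 33.3% of the autosomes, where gene density is generally higher than on the arms, held 554 of 1474 combined peaks (37.6%, interval 35.1 to 40.1; two-sided exact binomial test, p = 0.000609, adjusted p = 0.000812). The share was 41.9% on chromosome V, 40.6% on II, 36.7% on IV, 36.7% on I and 31.8% on III. On chromosome X, which was not part of this test, the central part held 109 of 380 peaks (28.7%, exact p = 0.0568). The replicate 1 list alone gave 41.0% (355 of 865, exact p = 2.21e-06). The call was not made in replicate 2 alone, at 33.3% of 111 peaks (interval 24.7 to 42.9, exact p = 1), or in combined peaks in both replicates, at 37.1% of 62 peaks (interval 25.2 to 50.3, exact p = 0.590), and both intervals hold the share of the combined list.

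**Figure D4:**
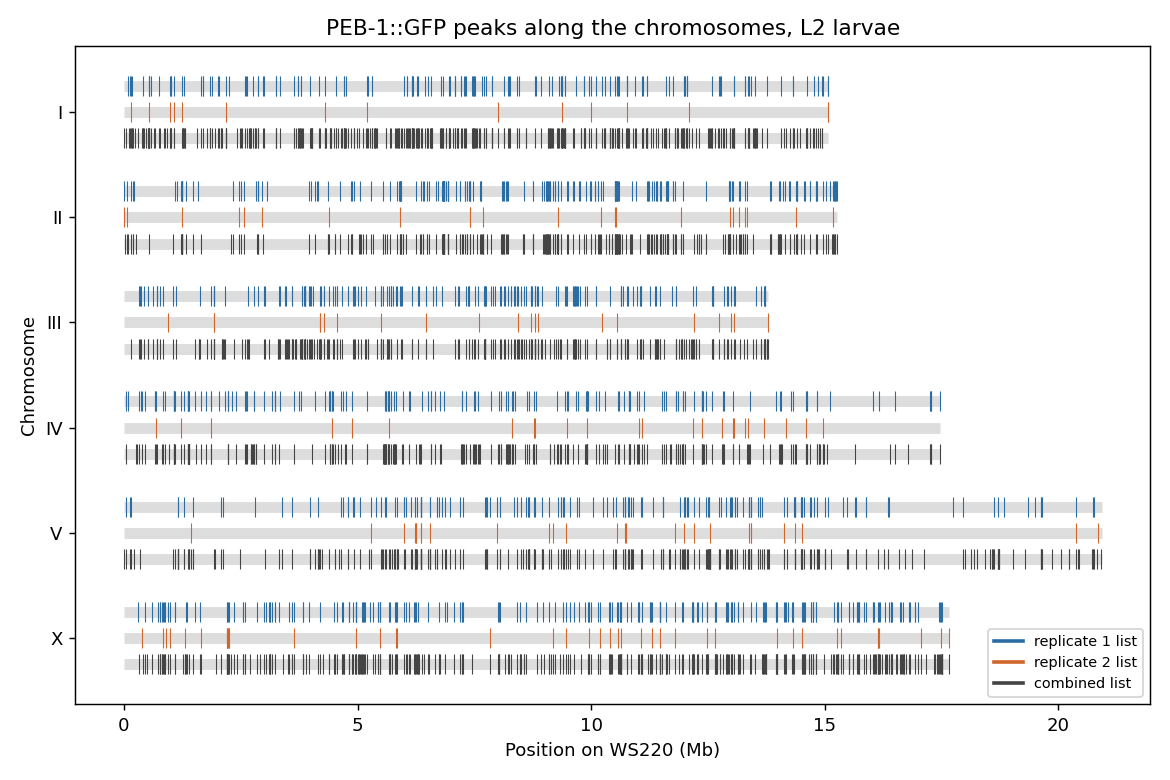
Positions of all peaks (vertical ticks) along the 6 nuclear chromosomes on WS220 (x axis, Mb), with the replicate 1, replicate 2 and combined lists as separate rows for each chromosome (y axis). The combined list holds 401 ticks on chromosome I where replicate 1 holds 157, and replicate 2 is sparse on all chromosomes, with 153 ticks in total.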

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

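The replicate overlap and the excess of peaks on chromosome X kept their direction and their side of the threshold under all alternatives run for them: 33.3% to 64.6% under 6 alternatives for the overlap, and 20.5% to 28.7% under 7 for chromosome X, with p from 8.40e-07 to 0.0124. For the central part of the autosomes, 5 of 7 alternatives kept the call. The replicate lists alone ranged from 33.3% (replicate 2) to 41.0% (replicate 1), and combined peaks in both replicates gave 37.1% on 62 peaks (exact binomial p = 0.590). Fewer peaks widen the interval for replicate 2 and for the peaks in both replicates. The replicate 2 share itself, however, was no higher than the 33.3% expected from length. The share of combined peaks that overlap replicate 1 was 67.4% among the 927 strongest combined peaks and 59.6% among peaks of at least 50 bp, and for replicate 2 it was 11.2% and 9.16%. The difference in median −log10 q by replication, a description only, was 4.56 to 4.63 under 3 alternatives. Halving each list left 927 combined, 547 replicate 1 and 76 replicate 2 peaks by construction. The alternatives that left out wide peaks, short peaks or chromosome I, merged neighbouring peaks, or used midpoints for the −log10 q difference were chosen after seeing the data. No paired analysis was possible because the inputs have no values of their own in these lists, so ChIP and input cannot be fitted with the replicate number as a block. The alternative that sets the X share against gene numbers was not run, since it needs a WS220 annotation. The alternatives run for the X share all use the deposited calls, so none tests whether peaks were called alike on all chromosomes. The lowest p-value for X came from leaving out chromosome I, which by itself raises the ratio of share to span on every other chromosome. Read depth is unknown, so a peak missing from a list, from replicate 2 above all, may have been undetectable at that list's depth and threshold. A missing peak therefore does not show that binding was absent. Peaks can be missing for other reasons too, since the combined list lacks the chromosome I region that led both replicates.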

Other observations

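Combined peaks were clustered along the chromosomes. There were 134 gaps of up to 1000 bp between neighbouring combined peaks, against a mean of 42.7 and a maximum of 64 in 1000 uniform placements (permutation p = 0.000999, the smallest these placements can give). Uniform placement ignores uneven features along the chromosomes, such as the central excess above, and a broad enrichment called in pieces would also give close gaps. The gaps therefore do not show that separate binding sites are clustered. Merging across gaps of up to 1000 bp gave 1720 regions, of which 102 held 2 peaks and 14 held 3 or more. The 2 regions with the most peaks, 5 each, were on chromosome X at 2200467 to 2219681 and on chromosome V at 6352462 to 6355666. The other regions with 3 peaks included one on chromosome X at 15274003 to 15277020 and one on chromosome III at 8799933 to 8802579, which contains the fifth strongest combined peak. The gap test, and the tests on chromosome V and on the chromosome X block below, were chosen after the values were seen. The chromosome I comparisons below were prompted by the surplus, after the counts were seen. Their gain in −log10 q is the difference already given above.

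The surplus of combined peaks on chromosome I is a pattern that a user of the combined list would want to check first. A candidate explanation is that chromosome I was scaled more permissively in the combined analysis. If so, peaks that replicate 1 also called should have gained more −log10 q on chromosome I than elsewhere, and they did, by a median of 1.58 more than on the other chromosomes (two-sided permutation p = 1e-05 over peaks, which are not independent units). Any other cause that lowered q values across chromosome I in the combined analysis, or raised them there in replicate 1, would give the same gain. The test therefore does not single out scaling, nor does it show which list is affected. An alternative is weak sites concentrated on chromosome I that replicate 1 also sees near its limit. Of the 548 weakest replicate 1 peaks, 15.7% (interval 12.7 to 19.0) lay on chromosome I. Among the combined peaks found in neither replicate the share was 28.6%. The lower share goes against this alternative only if replicate 1 called chromosome I as leniently as the other chromosomes, which is not known. Sites below the limit of replicate 1 are not counted either, so the alternative stays open. The region near the right end that led both replicates is absent from the combined list; whether this is linked to the surplus was not tested, and the design offers no biological contrast for chromosome I.

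The block of combined peaks within 20 kb of the strongest, on chromosome X, holds 7 peaks from 2196107 to 2225606, a length of 29500 bp of which 61.3% is covered by peaks, unlike the short peaks that make up most of the list. The peb-1 gene is on chromosome X, and the strain carries additional tagged copies of it, so extra copies of the tagged peb-1 carried by the transgene are a candidate explanation. Input from the same lysates holds the same copies, and the caller compares ChIP reads with a control library. How far that comparison offsets extra copies here is unknown. Binding of PEB-1 at this place stays open as well. The 2 cannot be told apart here, because no WS220 annotation was used, the extent of the transgene's insert is not given in the sources used here, and no input signal was analysed that would show copy number.

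The replicate 2 peak of 175768 bp at the right end of chromosome V is not matched in replicate 1, whose peaks cover 0.0762% of it. Replicate 1 had the longer list (1095 peaks against 153) and more peaks with q below 1e-05 (137 against 7). A generally shorter list therefore does not account for its low cover. Broad enrichment shared by both ChIP replicates is still not excluded, because read depth is unknown and a stretch without a call is not shown to lack signal. That many separate sites were joined into one call in replicate 2 may be an explanation. The combined list has 3 separate peaks there against 2.39 expected from the number on chromosome V (one-sided exact binomial p = 0.427). This count concerns the combined list and cannot show how replicate 2 made its call, so joining stays open. Elsewhere replicate 2 kept peaks separate at gaps down to 332 bp, and the 3 combined peaks cover only 0.199% of the stretch. The combined peaks there, at 20761747 to 20762005, 20830301 to 20830388 and 20905815 to 20905816, had q values from 2.06e-05 to 0.00961.

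Of the 11 combined peaks of 1000 bp or more, 2 that overlapped neither replicate had weak q values, on chromosome X at 2204299 to 2205956 (q = 0.00497, rank 1572 of 1854) and on chromosome III at 7446850 to 7447885 (q = 0.00595, rank 1628). The first of these lies within the chromosome X block described above. Another on chromosome III, 13778183 to 13781281 (3099 bp), had q = 4.42e-05 and overlapped replicate 2 only. Its end is the last peak position on chromosome III in any list. On chromosome V, 5283992 to 5285750 (1759 bp) had rank 916 in the combined list and rank 413 in replicate 1, but rank 4 in replicate 2.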
